A study of Drosophila melanogaster with 2 samples.

How the data were processed

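ChIP-seq was done in whole adult males of Drosophila melanogaster that express CG5204 (kmg) with eGFP at its C terminus, with an antibody against GFP, in 2 biological replicates of 1 group. Chromatin was sheared by sonication to fragments of 200 to 800 bp, per the labels. The labels name a control experiment, which is not analysed here. Whether the replicates came from separate cultures of flies is stated only as biological replicate numbers.

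The deposited files were peak lists in narrowPeak format on builds dm6 and dm3: for each build, a list of 30000 regions per replicate and for the pooled replicates, all including background, and a list of optimal IDR peaks. Peak signal values were deposited by the authors in these lists, and the deposited description derives them from alignments of the replicates and of control libraries. Significance was deposited by the authors as −log10 of the q-value of each region. The peak caller, its version, the aligner and the read filters are not given in the sources used here. The IDR peaks on dm6 were the 2868 regions of highest signal in the pooled list, and 2590 of them had the same width of 430 bp, so peak borders carry little information and summits were used. The IDR list depends on both replicates at once and has no error per replicate. Signal was used to rank, filter and describe peaks within lists, and was set side by side between replicates only for the same peak. Depth could not be judged, since read totals are not given in the sources used here.

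Coordinates are 1-based on dm6. The annotation was Ensembl release 115, on the Release 6 assembly that dm6 names, and each dm6 region lay within the lengths of its arms, with transposable elements left out: 18277 genes with 23697 TSSs, of which 13968 genes were protein-coding. Sequence came from the reference Release 6 genome. The dm3 lists entered only counts and comparisons among themselves, and no coordinates were converted.

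A promoter peak is a summit within 500 bp of a TSS. Shares were compared with 1000 circular shifts of the summits along each arm, with 1 random offset per arm (100 shifts for the replicates, 20 for annotation classes). Annotation at the summit was assigned in the order coding exon, 5' and 3' untranslated region, other exon, intron and intergenic. Medians of signal were compared by a two-sided permutation test with 100000 resamples. Gene lists, and X against 2L, 2R, 3L and 3R, were tested by Fisher's exact test, two-sided, on protein-coding genes, with conditional odds ratios and 95% intervals. Lists were adjusted by Benjamini-Hochberg over 29 lists, and 26 symbols of the lists were not found in the annotation and were left out. The 15 motifs were searched on both strands within 100 bp of the summit and in a window of the same size 500 bp downstream (exact McNemar test), and within 100 bp of the 5' ends of genes with and without a peak (Fisher's exact test). Intervals of shares are 95% Wilson intervals, and the limit for a share of 0 is 3 counts of the total. Both cover counting error only.

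Named items followed a rule fixed before the data were examined: kmg and Mi-2; the 20 protein-coding genes with the strongest promoter peak; up to 4 of the strongest members of each list past an adjusted p of 0.05, and up to 4 members without a peak for a list below the other genes; the 5 strongest peaks over 500 bp from every TSS; and each bound member of the spermatocyte regulators, of which there were 0. Some items that this rule takes are not reported here. Alternatives fixed at the same time were windows of 200 and 1000 bp, the 1434 strongest IDR peaks, the 2868 strongest regions of each replicate alone, 1 TSS per gene, shared promoters counted once, peaks over gene bodies, protein-coding TSSs only, matching within 300 bp or by at least 50% of both intervals, the dm3 lists, motif windows of 50 bp, an upstream flank and summits away from promoters. Chosen after seeing the data were peaks with a false discovery rate of at most 5%, genes with any region of the pooled list, and genes without a head-to-head neighbour within 1000 bp.

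Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. The code was tested on simulated data. For the list test on 13968 genes, 96% of planted lists of 60 genes were recovered and 2% of unplanted lists were called. For the promoter share over 2868 peaks a planted share of 56.3% was returned as 56.3%. That planted value was worked out with the same distance code on the same peaks, so this match checks little. For the replicate overlap a planted 58.4% was returned as 58.5%. For the motif test at 1000 summits a planted excess of 30 percentage points was returned as 29.9. For the median test with 600 values and no difference, 8% of runs passed 0.05.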

Results

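Chromatin immunoprecipitation with sequencing was carried out on whole adult male Drosophila melanogaster carrying a transgene for CG5204, the gene named kmg (kumgang), fused to eGFP. Kmg is a zinc finger protein known from spermatocytes, where it acts with the nucleosome remodeller Mi-2 to keep genes of other programmes off. The antibody was raised against GFP, and the control libraries were not analysed here, so the peaks are sites called in the GFP immunoprecipitation. The labels give 1 group with 2 biological replicates, and the comparisons are between those replicates and between classes of sites and genes. The peak list on build dm6 that passed the irreproducible discovery rate (IDR) held 2868 peaks, and the list on build dm3 held 2855. Peak signal is the value of the authors' peak caller and its scale is not given in the sources used here. Read totals were not given in these sources either, so the depth of each library is unknown, and intervals below cover only the counting of peaks and genes.

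The strongest sites were shared by both replicates. The highest peak in each replicate lay upstream of CG14100, with a signal of 766 in replicate 1 and 866 in replicate 2. Of the 2868 strongest regions of replicate 1, 1744 (60.8%, 95% Wilson interval 59.0 to 62.6) had a summit within 100 bp of 1 of the 2868 strongest of replicate 2. Circular shifts of the summits along each chromosome arm gave 0.442% (SD 0.137), and none of 100 shifts reached the observed share (one-sided permutation p = 0.00990, the smallest they can give). The IDR peaks were matched among the strongest regions of replicate 1 in 74.6% of cases and of replicate 2 in 76.8%. These 2 shares are partly built in, because the IDR peaks are the regions of highest pooled signal. That signal was close to the sum of the replicates' signals (median ratio of sum to pooled 0.992, SD 0.0821). For 2523 IDR peaks a region was listed in both replicates, and across these peaks, which are not independent replicates, Spearman's rho between the signals was 0.740. The ratio of replicate 1 to replicate 2 signal had a median of 0.961 and quartiles of 0.745 and 1.21. Signals differed more than 2-fold at 292 of these peaks (11.6%), but at only 9 of the 486 found in both lists among the 500 strongest. The false discovery rate in the pooled list was above 0.05 for 1079 of the 2868 peaks (37.6%), with 0.232 as the largest value.

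Peaks were concentrated near transcription start sites (TSSs), and those near protein-coding TSSs lay mostly upstream. Of the 2868 peaks, 1628 (56.8%, 95% Wilson interval 54.9 to 58.6) had their summit within 500 bp of an annotated TSS, against 13.6% (SD 0.786) for shifted summits. That is a 4.18-fold excess, and none of 1000 shifts reached it (one-sided permutation p = 0.000999, the smallest they can give). Around protein-coding TSSs, 1289 of 1550 summits (83.2%) lay on the upstream side, with a median distance of 129 bp upstream and quartiles of 46 and 227 bp upstream. Coding exons held the summit of 21 peaks (0.732%), against 17.1% (SD 0.698) for shifted summits. Introns held 47.4% against 43.4%, intergenic sequence 38.8% against 29.7%, and 5' untranslated regions 8.65% against 3.08%. Of the 1240 peaks over 500 bp from every TSS, 903 (72.8%) had their summit in an intron.

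**Figure D1:**
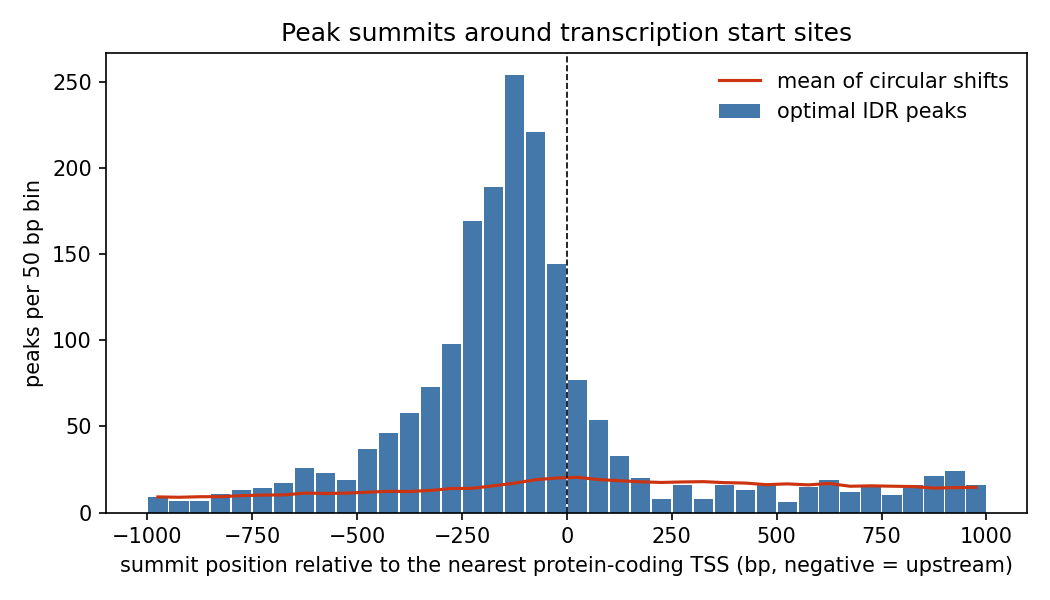
Bars give the number of dm6 IDR peaks per 50 bp bin by summit position relative to the nearest protein-coding TSS in bp, with negative positions upstream, and the line gives the mean of the circular shifts. The highest bar, from 150 to 100 bp upstream, holds 254 peaks against 17.1 for the shifts.

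Peaks at promoters were also the stronger ones. Their median signal was 81.7 (quartiles 55.7 and 145) against 65.5 (quartiles 50.1 and 99.4) elsewhere, a difference of 16.2 (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give). The share of peaks at promoters was 74.8% among the 286 strongest and 43.6% among the 287 weakest.

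The 20 protein-coding genes with the strongest promoter peaks had pooled signals from 648 to 1624.5, and 17 of the 20 summits lay upstream of the TSS. CG14100 led with 1624.5, at a peak on 3L from 19590426 to 19590819 whose summit lay in intergenic sequence 95 bp upstream. It was followed by mRpL41, a protein of the large mitochondrial ribosomal subunit, with a signal of 998 at a peak on 2R from 15217583 to 15217941 and its summit 145 bp upstream. Tcs5, a subunit of the complex that makes a threonylcarbamoyl modification of tRNA, had 964 on 3L from 5139330 to 5139677, shared with CHMP2B of the endosomal sorting machinery. The ribosome maturation factor eIF6 had 937 on 2R from 23850244 to 23850565, with the summit 94 bp upstream, in an exon of the antisense RNA gene asRNA:CR45928. Pdrg1, which shares its peak with Pal1, had 933, and the arginine methyltransferase Art3, which shares its peak with mRpS10 of the small mitochondrial ribosomal subunit, had 848. CG31145 had 832, CG1888 had 788, the HMG-box factor Sox14 had 780, and CenG1A, sharing with mRpS23, had 738. The UDP-galactose transporter Ugalt had 736, CG1635 had 719, the piRNA pathway protein papi had 705 and Hpf1, a cofactor of poly(ADP-ribose) polymerase, had 702. The chromodomain protein Chro, sharing with the TFIIH subunit Ssl1, had 692. Hrd3, of protein degradation at the endoplasmic reticulum, had 666 and shares with PTPMT1. The last were CG11309 with 659, CG8360 with 657, CG5611 with 656 and Drat with 648. In 9 of the 20, a second protein-coding gene had a TSS within 500 bp of the summit. For 19 of the 20 the peak ranked in the first 40 of both replicates, which their choice by pooled signal favours. The exception was Sox14, with 413 in replicate 2 and no region matched in replicate 1. At peaks listed in both replicates, the summed signals were close to the pooled signal (median ratio 0.992). The 413 alone falls well short of the pooled 780, so the missing entry does not show that replicate 1 lacked signal there.

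**Figure D2:**
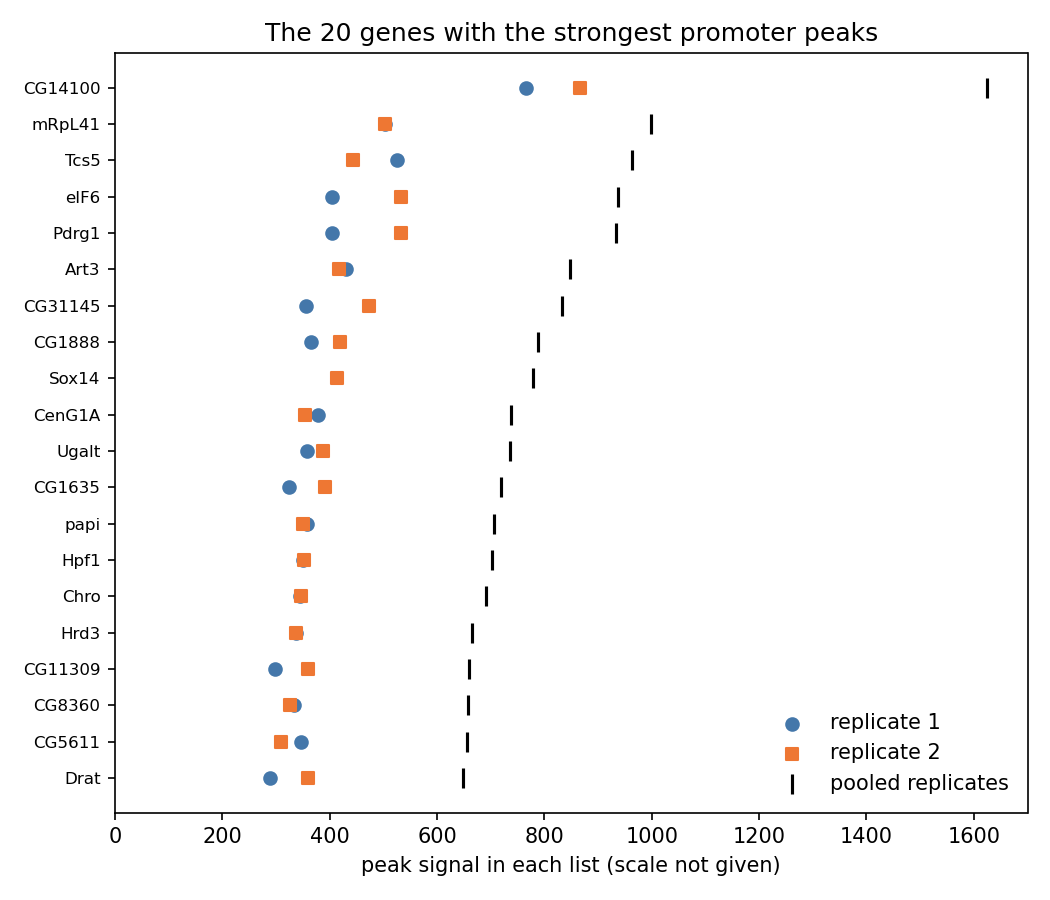
For the 20 genes with the strongest promoter peaks, circles give peak signal in replicate 1, squares in replicate 2 and ticks in the pooled replicates, on a scale not given in the sources. CG14100 is highest in each list at 766, 866 and 1624.5, and Sox14 has no circle because no replicate 1 region matched its peak.

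The 5 strongest peaks over 500 bp from every TSS all had their summit in an intron. The first, with a signal of 1367.7, lay in CG11050 on 2L from 6612475 to 6612910, 1026 bp from the nearest TSS. The others lay in Trl, which encodes GAGA factor, on 3L from 14759321 to 14759715 (1010.4), and in the kinase gene Lk6 on 3R from 11760891 to 11761222 (976). The remaining ones lay where the HMG-box genes HmgD and HmgZ overlap on 2R from 21703191 to 21703648 (943) and in CG12769 on 2R from 8060837 to 8061193 (758).

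The tagged gene itself and its known partner had no IDR peak. No region of any of the 4 dm6 lists lay in kmg (2L from 13160527 to 13163153) or within 500 bp of it, and the nearest IDR summit was 61155 bp from its 5' end. Mi-2 (3L from 19882051 to 19910215) had none in the IDR, pooled and replicate 2 lists and 2 among the 30000 regions of replicate 1, a list that includes background.

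Because males carry 1 X chromosome, X-linked genes were compared with autosomal ones. Of 13968 protein-coding genes, 1748 (12.5%, 95% Wilson interval 11.98 to 13.07) had a promoter peak. The share was 280 of 2196 (12.8%) on the X and 1450 of 11669 (12.4%) on 2L, 2R, 3L and 3R, and the odds ratio was 1.03 (95% interval 0.895 to 1.18, Fisher's exact two-sided p = 0.673). By the same exact test, the odds ratio lay below 1 and past the threshold among the 1434 strongest peaks (0.804, p = 0.0167) and in replicate 1 alone (0.851, p = 0.0197), though not in replicate 2 alone (1.06, p = 0.390). At a false discovery rate of at most 5% it was 0.905 and did not pass (exact test, p = 0.232). Chromosome 4 had 18 of 80 genes with a peak (22.5%, interval 14.7 to 32.8). The Y chromosome had 0 of 23, but it held only 1 of the 30000 regions of the pooled list, so binding there was not assessable.

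Among 29 gene lists fixed before the data were examined, genes of the cytoplasmic ribosome stood above the rest. Promoter peaks lay at 29 of 86 ribosomal protein genes (33.7%, 95% Wilson interval 24.6 to 44.2), with an odds ratio of 3.60 (2.21 to 5.74) against all other protein-coding genes. Fisher's exact test, adjusted by Benjamini-Hochberg over the 29 lists, gave p = 3.94e-06. In 24 of the 29 the summit lay upstream of the TSS, at a median of 63 bp upstream over all 29, and 27 had a region in both replicates. Among the strongest were RpS27 with a signal of 393 on 3R from 25247417 to 25247659, RpL34b with 334 and RpL14 with 249. Genes that share a promoter share a peak, so genes are not fully independent in these tests. With peaks counted in the 11 alternatives the odds ratio stayed between 2.67 and 5.81.

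Circadian clock genes also had peaks more often than other genes, on a small count. Of 14 members, 6 had one (42.9%, 95% Wilson interval 21.4 to 67.4), with an odds ratio of 5.26 (1.501 to 17.3) and an adjusted p of 0.0271 by Fisher's exact test. These were the blue light receptor gene cry with a signal of 332, the kinase gene sgg with 206, the transcription factor gene Pdp1 with 126 and per, a core repressor of the clock, with 96.8, and also tim with 46.7 and vri with 45.6, which were named after their values were seen. All 6 summits lay over 200 bp from the TSS, so that 0 of 14 had a peak when the window was 200 bp. The call also ended without replicate 2 (exact test, adjusted p = 0.101), among the 1434 strongest peaks (0.156), at a false discovery rate of at most 5% (0.151) and with 1 TSS per gene (0.495).

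Chemosensory genes, which include odorant, gustatory and ionotropic receptors and odorant-binding proteins, almost lacked promoter peaks. Of 230 members, 2 had one (0.870%, 95% Wilson interval 0.239 to 3.11), with an odds ratio of 0.0603 (0.00725 to 0.221, adjusted p = 9.11e-10 by Fisher's exact test). These were Obp99b with a signal of 51.9 and Gr39b with 43.7. Or85c, Gr93c, Obp99a and Gr89a were among those without a peak. The list of testis paralogs of housekeeping complexes was drawn up by gene name, without a check for expression in the male germ line. It holds 49 genes, of which 7 are also in another list. Promoter peaks lay at 0 of the 49 genes, which allows a share of up to 6.12% (exact test, adjusted p = 0.0151). Prosalpha3T, Prosalpha4T1, Prosalpha4T2 and Prosalpha6T, which are proteasome subunits, were among them. That call ended in the exact tests with 200 bp windows (adjusted p = 0.116), among the 1434 strongest peaks (0.159), at a false discovery rate of at most 5% (0.0930), with 1 TSS per gene (0.0630) and without head-to-head genes (0.246). Replication-dependent histone genes had 0 of 111, including His2A:CG33832, His1:CG33816, His3:CG33803 and His2A:CG33820 (exact test, adjusted p = 6.76e-06). The histone cluster on 2L from 21416953 to 21541681 held no region of any list, where 32.1 regions of the pooled list would lie at the mean density of the arm, so binding there was not assessable.

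**Figure D3:**
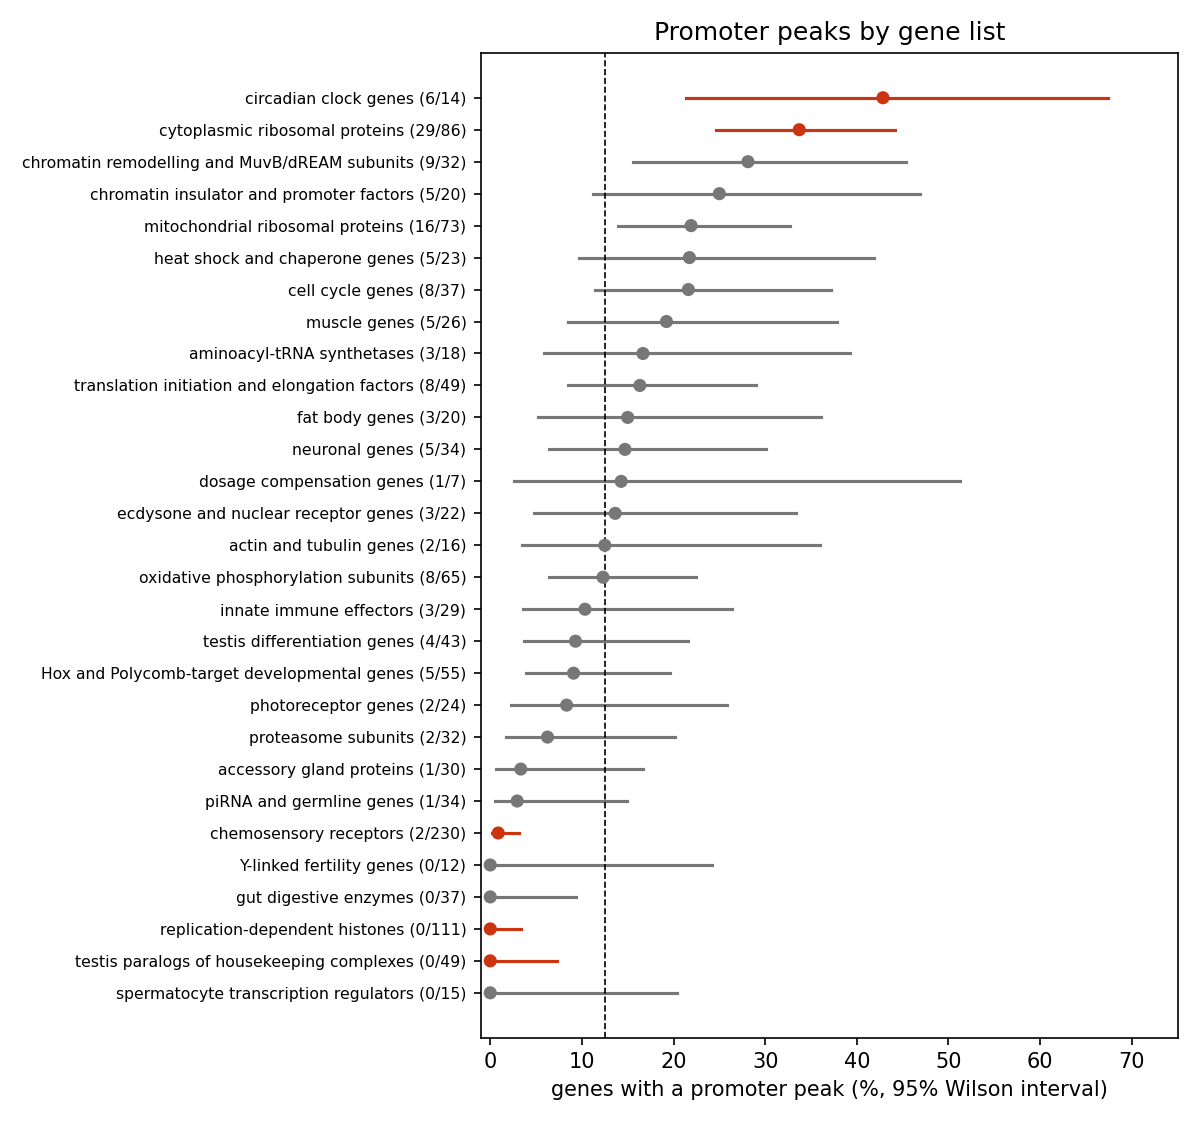
Each row is a gene list with the number of its genes that have a promoter peak over all members, points give the percent and lines the 95% Wilson interval, and the dashed line marks all protein-coding genes at 12.5%. Red marks the 5 lists past an adjusted p of 0.05, with clock genes at 42.9% and ribosomal protein genes at 33.7% on the right of the line.

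The other 24 lists did not pass. No spermatocyte transcription regulator had a peak (0 of 15, which allows a share of up to 20%, exact test, adjusted p = 0.502), and testis differentiation genes had 4 of 43 (9.30%, adjusted p = 0.856). Gut digestive enzymes had 0 of 37 (exact test, adjusted p = 0.0553). Chromatin remodelling and MuvB/dREAM subunits had 9 of 32 (28.1%, exact test, adjusted p = 0.0583), mitochondrial ribosomal proteins had 16 of 73 (21.9%, adjusted p = 0.0747) and insulator and promoter factors had 5 of 20 (25%, adjusted p = 0.307). The gut, remodelling and mitochondrial ribosomal lists each passed in replicate 1 alone (adjusted p from 0.0205 to 0.0307) and in replicate 2 alone (0.00266 to 0.0381) by the exact test. Insulator and promoter factors passed in replicate 2 alone (odds ratio 3.56 against 2.33, exact test, adjusted p = 0.0381). Cell cycle genes had 8 of 37, piRNA and germline genes had 1 of 34 (both with an exact test's adjusted p = 0.337), heat shock and chaperone genes had 5 of 23 (0.442) and accessory gland proteins had 1 of 30 (0.407). Oxidative phosphorylation subunits had 8 of 65, translation factors had 8 of 49, proteasome subunits had 2 of 32 and aminoacyl-tRNA synthetases had 3 of 18. Among lists of tissues, neuronal genes had 5 of 34, muscle genes 5 of 26, photoreceptor genes 2 of 24, fat body genes 3 of 20 and innate immune effectors 3 of 29. Hox and other developmental genes had 5 of 55, ecdysone and nuclear receptor genes 3 of 22, actin and tubulin genes 2 of 16 and dosage compensation genes 1 of 7. Y-linked fertility genes had 0 of 12, on a chromosome where binding was not assessable.

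Genes with a promoter peak differed from genes without in the core elements at their 5' ends. The peak of a gene can lie at a TSS other than this 5' end. Ohler Motif 7 lay within 100 bp of the 5' end at 24.3% of the 1748 genes with a promoter peak and at 13.9% of the 12220 without (odds ratio 1.99, 95% interval 1.76 to 2.25, adjusted p = 1.3e-25 by Fisher's exact test over 15 motifs). The E-box of Ohler Motif 5 followed (18.5% against 13.1%, odds ratio 1.51), and the E2F site, the BEAF-32 site, the GAGA element, the M1BP element and the Dref element (DRE) were also more frequent, with odds ratios from 1.25 to 1.34. The GC control word had an odds ratio of 1.19 (95% interval 1.00 to 1.40, exact test, adjusted p = 0.0672), an interval that spans those 1.25 to 1.34. The AT control word had 1.05 (0.925 to 1.18). By the exact test, the M1BP call (odds ratio 1.28) ended among the 1434 strongest peaks (1.28, adjusted p = 0.0648) and at a false discovery rate of at most 5% (1.25, adjusted p = 0.0626). The DRE call (odds ratio 1.25) ended in the same settings (1.18 and 1.19, exact test, adjusted p = 0.179 and 0.129). The GAGA call (odds ratio 1.34) ended without replicate 2 (1.29, exact test, adjusted p = 0.0506) and with 50 bp windows (1.54, adjusted p = 0.0604). The TATA box (9.61% against 14.7%, odds ratio 0.615, exact test, adjusted p = 1.28e-08) and the initiator (24.3% against 30.2%, odds ratio 0.741) were less frequent. Of the 15 motifs, 7 were higher, 2 were lower and 6 did not pass. Each DRE site also counts as a BEAF-32 site, whose word it contains, so those calls are not independent.

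At the summits themselves, 8 motifs were more frequent than 500 bp downstream, 4 were less frequent and 3 did not pass the exact McNemar test. Sequence within 100 bp of the summit was richer in A and T than the flank, with a mean GC content of 35.7% (SD 7.02 over peaks) against 43.1% (SD 9.19), and the AT control word was more frequent there by 10.9 percentage points. The TATA box, itself rich in A and T, lay at 14.9% of summits and 7.43% of flanks (exact test, adjusted p = 5.76e-18), and with promoter peaks left out the difference was 4.76 percentage points (adjusted p = 0.000742). Ohler Motif 7 lay at 11.5% of summits and 6.00% of flanks (exact test, adjusted p = 5.12e-13), the BEAF-32 site at 12.8% and 7.22%, and the DRE at 3.14% and 0.732%. The BEAF-32 word lies within the DRE word, so each DRE site was also counted as a BEAF-32 site. The BEAF-32 site and the DRE are also rich in A and T, and the flank was not matched in base composition. With promoter peaks left out, Motif 7, the BEAF-32 site, the DRE and the M1BP element no longer passed the exact test, with adjusted p from 0.566 to 1. The GAGA element was less frequent at summits than in the flank (3.97% against 5.61%, exact test, adjusted p = 0.00589), as were the GC control word, the CA repeat and the E2F site. The GAGA call at summits, a difference of -1.64 percentage points, ended without replicate 1 (-1.12, exact test, adjusted p = 0.0809). The M1BP call there, a difference of 0.837 points, ended among the 1434 strongest peaks (0.767, exact test, adjusted p = 0.0884).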

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

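Each result was recomputed with 1 choice changed at a time. The false discovery rate limit, the restriction to genes with any region of the pooled list, the removal of head-to-head genes, and all alternatives for the number of genes with a peak and for motifs at bound promoters were chosen after seeing the data. The share of peaks at promoters stayed above the shifts in all 7 of its alternatives (36.0% to 68.2%). Promoter peaks stayed stronger in all 6 of theirs, with a difference of 16.7 to 27.4 in pooled signal. The differences of 8.79 in replicate 2 alone and 8.87 in replicate 1 alone are on a lower scale of signal. The highest signals there were 866 and 766, against 1624.5 in the pooled list, so these values do not show a weaker effect. The replicates matched more often than shifts in all 4 alternatives (58.5% to 70.4%). Ribosomal protein and chemosensory genes kept their calls in all 11 alternatives of the lists. For the results below that did not keep theirs, the cause was not tested, except that fewer peaks or genes enter where a setting removes them. Among the 1434 strongest peaks, 1121 genes had a promoter peak against 1748, 3 lists passed against 5, and the odds ratio was 0.804 for the X, 4.60 for clock genes and 0 for testis paralogs. At a false discovery rate of at most 5% 3 lists passed, and these odds ratios were 0.905, 3.85 and 0. With 200 bp windows 1147 genes had a peak, 3 lists passed, and the odds ratios were 0.919, 0 and 0. With 1 TSS per gene 3 lists passed, and the odds ratios were 0.992, 2.25 and 0. Clock genes had 4.61 among genes with any pooled region. Without head-to-head genes 864 genes had a peak, and testis paralogs and histones, at an odds ratio of 0, no longer passed. With 1 replicate left out at a time, the odds ratio ranged from 0.851 to 1.06 for the X and from 3.35 to 4.96 for clock genes, and 7 to 9 lists passed. With promoter peaks left out 7 motifs passed against 12, and the differences turned to -0.242 percentage points for M1BP and -0.0806 for Motif 7. Of 311 list alternatives, 34 changed sign without being past the threshold in either setting, and 16 brought a list past it that was not. Of 180 motif alternatives, 15 lost and 7 gained a call. No paired analysis was possible because there is 1 group. Depth is unknown, and the control libraries were not analysed here.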

Other observations

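The groups in this part were chosen after the data were seen. Genes with a head-to-head neighbour, whose 5' ends lie within 1000 bp on opposite strands, had a promoter peak in 884 of 4650 cases (19.0%) against 864 of 9318 (9.27%) for the others, with an odds ratio of 2.30 (95% interval 2.07 to 2.54, Fisher's exact p = 2.23e-57). A shared peak counts for both neighbours, so this ratio is partly built in. Mitochondrial ribosomal protein genes had peaks at 15 of 56 head-to-head members and at 1 of the 17 others. Genes known only by a CG number had a peak in 8.68% of 6104 cases, against 15.5% of 7864 genes with a name (odds ratio 0.519, 95% interval 0.465 to 0.579). On chromosome 4, where the odds ratio against the large autosomal arms was 2.05 (1.14 to 3.52, Fisher's exact p = 0.0105, unadjusted), the bound genes included RpS3A, the Polycomb recruiter pho, the eye selector gene ey and gw of the microRNA pathway.

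Among 27 symbol families with at least 20 genes, cuticle proteins of the Cpr family had a peak at 0 of 70 genes (Fisher's exact test, adjusted p = 0.00152 over the families). Large subunit genes of the cytoplasmic ribosome (RpL) had 19 of 50 and small subunit genes (RpS) 10 of 38 (exact test, adjusted p = 5.6e-05 and 0.0664). In the mitochondrial ribosome, small subunit genes (mRpS) had 10 of 26 (exact test, adjusted p = 0.00328) and large subunit genes (mRpL) 6 of 47 (odds ratio 1.02, 95% interval 0.354 to 2.43, adjusted p = 1). Of genes that encode no protein, 11 of 290 tRNA genes, 6 of 269 snoRNA genes and 126 of 3289 other non-coding RNA genes had a promoter peak. Of the 28 IDR peaks with no region of replicate 1 within 300 bp, 6 with signal above the list's median had a replicate 2 signal of 0.535 times the pooled signal (median), Sox14 among them, against 0.505 for peaks found in both and 0.738 for the 21 weaker ones that a replicate 2 region matched. For the 35 with no region of replicate 2, the values of replicate 1 were 0.496 for 10 stronger peaks, 0.675 for 24 weaker ones and 0.484 for peaks found in both. At the stronger peaks these values were near those of peaks found in both, so a missing entry there does not show missing signal.

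For the 3 patterns below no biological explanation was tested, since the labels give 1 group. Tests chosen after the result was seen were those of ribosomal genes without a head-to-head neighbour and against other machinery and mitochondrial ribosomal genes, the signal of X-linked genes, CACTGT away from promoters and both tests of base composition.

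Ribosomal protein genes had promoter peaks more often than other genes. Shared promoters are argued against as the whole cause, because among genes without a head-to-head neighbour 12 of 34 had a peak (35.3%) and the odds ratio was 5.40 (95% interval 2.43 to 11.4). A like rate at any gene of the basic cell machinery is argued against too, because proteasome, oxidative phosphorylation, translation factor and tRNA synthetase genes together had 21 of 164 (12.8%), and the odds ratio against them was 3.45 (1.74 to 6.93). That set left out the mitochondrial ribosome, and with it included the odds ratio was 2.74 (1.49 to 5.03, 37 of 237), but against its 73 genes alone it was 1.81 (0.843 to 3.97), so a rate shared by both ribosomes stays open. High transcription, or open chromatin that any tagged protein could reveal, stays open, since no expression values or control libraries were analysed here.

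X-linked genes were fewer among those with the strongest peaks, at 149 of 2196 (6.79%) against 969 of 11669 autosomal genes (8.30%) for the 1434 strongest peaks. At a false discovery rate of at most 5% the odds ratio was 0.905 and did not pass Fisher's exact test (p = 0.232). In replicate 2 alone it was 1.06 (exact test, p = 0.390). A uniform loss of signal from the single X copy may be asked about first. If copy number alone set the signal, with no background in it, the value reached by the top 10% of X-linked genes would be 0.5 of that of autosomal genes. It was 0.915 (95% bootstrap interval 0.800 to 1.07), so copy number without any background did not set the signal at that level. The values compared there (52.5 and 57.3) lie near the weakest IDR peak (42.5), and the scale and background of the signal are not given. A uniform loss above background is therefore not decided by this ratio. The ratio was 0.794 (0.648 to 0.964) for the top 5% and 0.612 (0.490 to 0.721) for the top 1%. A loss from the single copy, at all sites or limited to the strongest, stays open.

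The 6-mer CACTGT, picked with its window because it was frequent in these same peaks, lay within 150 bp of 710 of 2868 summits (24.8%) and of 409 points 500 bp downstream (14.3%), a ratio of 1.74 (95% bootstrap interval 1.55 to 1.94). Exact matches of Ohler Motif 7 are argued against as the source, since with them masked 686 summits kept the 6-mer and the ratio was 1.71 (1.52 to 1.92). Looser matches of Motif 7 were not masked, so they stay open. Whether promoters in general carry it stays open, because the ratio of 1.66 (1.43 to 1.96) at the 1240 peaks over 500 bp from every TSS and the odds ratio of 1.71 (1.46 to 2.00) from 50 to 250 bp upstream of genes with against without a peak both read again the sequence that prompted the choice. The 179 other 6-mers of the same bases had a median ratio of 0.908, so base composition did not raise such words in general. Because CACTGT was picked for its frequency in these peaks, its excess over them cannot decide on base composition. In the test set first, 2 of them were as high as the interval of CACTGT (CTGTAC, and CGATAG at 1.815, which overlaps the DRE and BEAF-32 sites). The median was added after that result. A binding site of the tagged protein or of a partner stays a candidate explanation only. Sites were fewer within 49 bp of the summit (228) than from 50 to 99 bp (361) or 100 to 149 bp (322). These counts were not set against base composition, so they do not decide whether a site lies under the summit.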
